A study of Mus musculus with 39 samples.

How the data were processed

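RNA was measured in 39 samples of CD68-rich tissue cut by laser capture from 6 µm sections of aortic roots of female Apoe-deficient mice. The mice ate a high-cholesterol diet for 12 weeks and then received 4 intravenous injections over 7 days, and tissue was taken 24 hours after the last injection. The labels give 4 groups: PBS (10 samples), TRAF6i-HDL (10), mTORi-HDL (10) and S6K1i-HDL (9), where the inhibitors were carried by high-density lipoprotein (HDL) nanoparticles at 5 mg/kg of drug. The protocol text names the drugs as CD40-HDL, rapamycin-HDL and PF-4708671-HDL, and an empty particle that none of these samples carries. A difference between an inhibitor and PBS therefore cannot be separated from an effect of the HDL carrier. The RNA was amplified as whole transcriptomes before sequencing. CD68 staining was used to choose the captured regions, so the level of Cd68 is no finding about the groups.

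The deposited files hold raw read counts per gene, 1 file per sample and without a header. Each lists 24062 mouse gene symbols and 5 closing lines on reads not assigned to a gene. Per the labels, the authors used TopHat2 2.1.0, Bowtie2 2.2.8 and HTSeq 0.6.1, with no role or order stated. The labels also name hg19 as the build, a human assembly that cannot be the one behind mouse symbols. The mouse build, annotation version, strand setting and filters are not stated, so no coordinates are given for any gene.

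Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Genes were kept by filterByExpr over the 4 groups, which left 10411 genes, and libraries were scaled by TMM factors. All 39 samples were fitted together with group as the only term (estimateDisp, glmQLFit and glmQLFTest, robust). Genes passed at a Benjamini-Hochberg adjusted p under 0.05. The error of a log2 fold change is a standard error, taken as its size divided by the root of the F statistic, and levels are TMM-scaled CPM values with standard deviations. Log2 CPM used a prior count of 2. The 6 comparisons were each inhibitor against PBS and each pair of inhibitors.

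Gene lists were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the lists. Of 41 lists, 40 had tested members, and the list of mitochondrially encoded transcripts had 0, because none of its 13 members was tested. Each test was repeated with the correlation estimated from the data, and with fry, which asks whether the genes of a list moved on balance one way without comparing them with other genes. The groups, the 6 comparisons, the tests, the lists and the rule for named genes were chosen before the data were examined.

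The named genes were, for each inhibitor against PBS, the 10 with the smallest p in each direction among genes past the threshold with a mean log2 CPM of at least 3 and a regular symbol. Where fewer than 5 genes passed, the 10 genes with the smallest p were named whether or not they passed. Each pair of inhibitors had 5 in each direction. The rule added the 3 members with the smallest p of each list that passed, 1 passing member of each other list, and Traf6, Cd40, Mtor, Rps6kb1, Psap and Cd68, with Apoe as a check of the strain. It gave 329 results. The examples described here were picked from these after their values were seen, with preference for genes whose call held when any 1 library was left out.

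Total counts in genes, detected genes and the share of the 100 most abundant genes were compared with PBS by two-sided permutation tests, with 100000 resamples for 10 against 10 samples and exact for 9 against 10. The share of counts in Rn45s, a ribosomal RNA gene, and the shares of reads outside genes or with several alignments were compared in the same way after the data were seen. Each family of 9 tests was adjusted separately.

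Alternatives fixed in advance were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-voom with quality weights, no low-count filter, a stricter filter (at least 5 CPM in 9 samples), a replicate block, the number of detected genes as a covariate, only the 2 groups compared, an adjusted p under 0.2, a log2 fold change of at least 1, and each of the 39 libraries left out in turn. Added after the data were seen were the log2 Rn45s share as a covariate, the same without the 3 libraries under 200000 counts, those 3 libraries left out alone, Rn45s left out of the counts, and offsets for the trend of each library on GC content and transcript length. GC content and length came from a mouse transcript reference matched by symbol, which covered 9969 of the tested genes (95.8%). In a further fit added then, mTORi-HDL replicates 1 to 4 and 5 to 10 and S6K1i-HDL replicates 1 to 6 and 7 to 9, which the series lists apart, were taken as separate groups. The tests of the means of gene lists in the closing part left out the 3 libraries under 200000 counts and were repeated on all 39, and an explanation was taken as excluded only where both did so. The labels do not say whether replicate numbers pair samples, and samples were treated as unpaired. Across 48 pairs of samples with the same number in different groups, the median correlation of what the groups left unexplained was 0.0155. It ranged from -0.280 to 0.388, with 13 pairs over 0.1, so pairing of some samples is not excluded.

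The calls were tested on simulated data with the depths of these libraries. With 10405 genes tested, changes of 2-fold were recovered for 68.7%, 56.7% and 74.6% of altered genes in the TRAF6i-HDL, mTORi-HDL and S6K1i-HDL comparisons with PBS, and changes of 1.5-fold for 26.9%, 28.4% and 20.9%. Intervals and limits given for single libraries cover counting error only, since amplified reads without molecular identifiers are not independent molecules. The labels do not tie samples to animals, so each p measures the spread between samples, part of which may come from tissue of the same animal.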

Results

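Whole-transcriptome RNA sequencing covered 39 samples of CD68-rich plaque tissue from the aortic roots of Apoe-deficient mice. They came from mice given PBS (n = 10) or HDL nanoparticles carrying an inhibitor of TRAF6 (an adaptor of CD40 signalling, n = 10), of mTOR (a growth-control kinase, n = 10) or of S6K1 (n = 9). S6K1, encoded by Rps6kb1, is a kinase downstream of mTOR. The 6 comparisons address how the transcript levels in these plaque regions differ between each inhibitor and PBS and between inhibitors. Errors after log2 fold changes are standard errors, and errors after CPM values or shares are standard deviations.

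Depth differed between the groups. Counts in genes were 1388061 ± 938986 in PBS (range 50091 to 3314493), 1836638 ± 1121559 in TRAF6i-HDL (66602 to 3977229), 3200136 ± 996972 in mTORi-HDL (1825755 to 4875794) and 4479531 ± 1866779 in S6K1i-HDL (118527 to 6833491). The difference from PBS had an adjusted permutation p of 0.442 for TRAF6i-HDL (above the PBS mean in 7 of 10 samples), 0.00297 for mTORi-HDL (10 of 10) and, by the exact test, 0.00297 for S6K1i-HDL (8 of 9). Detected genes numbered 12297 ± 2148, 12668 ± 2144, 14000 ± 457 and 13760 ± 2075 in the same order (adjusted p = 0.697, 0.00342 and exact 0.254). The 100 most abundant genes held 53.2% ± 6.03, 55.1% ± 6.19, 59.0% ± 6.37 and 66.0% ± 7.92 of the counts (adjusted permutation p = 0.536, 0.0914 and exact 0.00446). Rn45s, ribosomal RNA that may be precursor or mature, took 13% ± 10.9 of the counts in PBS, 17.8% ± 8.31 in TRAF6i-HDL, 23.1% ± 7.81 in mTORi-HDL and 37.0% ± 10.3 in S6K1i-HDL. Against PBS the adjusted permutation p was 0.308, 0.0729 and (exact) 0.00229, and 7 of 10, 8 of 10 and 9 of 9 samples lay above the PBS mean. Reads with several alignments made up 15.5% ± 1.48, 16.7% ± 2.35, 17.1% ± 2.07 and 19.4% ± 1.57 (adjusted permutation p = 0.252, 0.102 and exact 0.000779). Reads outside genes made up 53.2% ± 4.80, 51.4% ± 4.06, 49.4% ± 5.25 and 47.8% ± 4.86 (adjusted permutation p = 0.389, 0.17 and exact 0.0729). Apoe, the gene inactivated in the strain, was at 4.56 ± 3.92 CPM in PBS, 5.99 ± 4.80 in TRAF6i-HDL, 3.46 ± 2.73 in mTORi-HDL and 4.60 ± 2.64 in S6K1i-HDL.

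**Figure D1:**
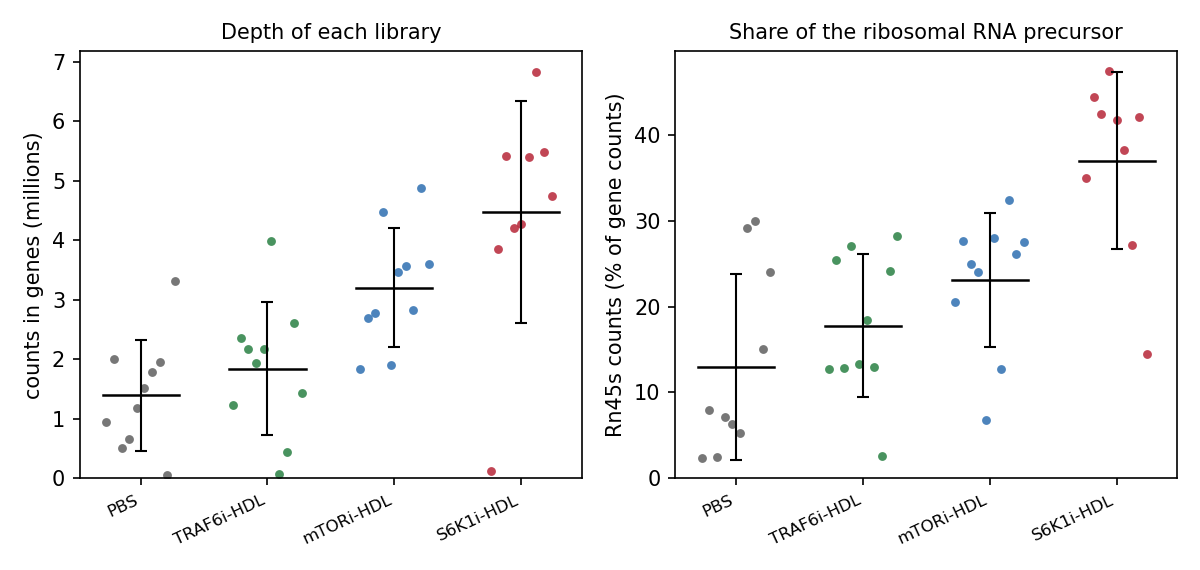
Counts in genes (left) and the share of counts in Rn45s (right, %) of each library, with the mean and standard deviation of each group. Means of the Rn45s share were 13% in PBS, 17.8% in TRAF6i-HDL, 23.1% in mTORi-HDL and 37.0% in S6K1i-HDL.

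Under TRAF6i-HDL, Stab1, a scavenger receptor of macrophages and sinusoidal endothelium, was higher than in PBS. Its level was 117 ± 49.3 CPM against 52.5 ± 20.7, a log2 fold change of 1.12 ± 0.19 (n = 10 and 10, adjusted p = 0.00238, above the PBS mean in 8 of 10 samples). Ninl, which encodes a protein of the centrosome, was lower at 10.3 ± 2.13 CPM against 25.9 ± 18.5, a log2 fold change of -1.15 ± 0.23 (adjusted p = 0.0425, below the PBS mean in 10 of 10 samples). These 2 genes were the ones past the threshold of 10411 tested, 1 higher and 1 lower, while 1158 had an unadjusted p under 0.05, where 521 are expected by chance. The macrophage marker list had 0 of 24 members past the threshold over all genes and 2 higher when adjusted over the list alone. Its median was 0.19 (adjusted p = 0.00471, and adjusted p = 0.809 with an estimated correlation). Over all samples its mean log2 CPM was above PBS by 0.28 ± 0.16 (standard error), that of B cell markers by 0.81 ± 0.30, of T and NK cell markers by 0.44 ± 0.36 and of adipocyte markers by 0.17 ± 0.19. Without the 3 libraries under 200000 counts these were 0.18 ± 0.10, 0.64 ± 0.25, 0.46 ± 0.23 and 0.26 ± 0.10, and the last 3 lists did not pass (adjusted p = 0.153, 0.46 and 0.163). Among its members, Emr1, which encodes F4/80, was at 0.60 ± 0.15 (adjusted p = 0.159, above the PBS mean in 10 of 10 samples) and Laptm5, a lysosomal membrane protein of blood cells, at 0.43 ± 0.16 (adjusted p = 0.308, 8 of 10). The list of efferocytosis and phagocytosis receptors had Stab1 as its 1 higher member of 27, or 3 higher and 2 lower when adjusted over the list alone. The median of the list was 0.11 (adjusted p = 0.0388, and adjusted p = 0.809 with an estimated correlation). Mertk, a receptor for apoptotic cells, was at 0.65 ± 0.18 (adjusted p = 0.174, 9 of 10) and Stab2, a scavenger receptor related to Stab1, at 1.38 ± 0.39 (adjusted p = 0.174, 9 of 10). The unfolded protein response list had 0 of 21 members past the threshold, or 2 higher and 5 lower when adjusted over the list alone. Members had a median of -0.20 (adjusted p = 0.0388, and adjusted p = 0.809 with an estimated correlation). Sdf2l1, an endoplasmic reticulum chaperone component, was at -0.72 ± 0.18 (adjusted p = 0.153, below the PBS mean in 10 of 10 samples). Syvn1, a ligase that marks misfolded proteins for degradation, was at 0.76 ± 0.22 (adjusted p = 0.178, 10 of 10), and Pdia4, a disulfide isomerase, at -0.55 ± 0.18 (adjusted p = 0.233, 10 of 10). Pltp, the phospholipid transfer protein, was at 1.00 ± 0.23 (adjusted p = 0.115, 8 of 10). The genes of the targeted pathway did not pass: Traf6 was at 0.14 ± 0.17 (adjusted p = 0.799) and Cd40 at -0.10 ± 0.46 (adjusted p = 0.977).

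With the Rn45s share as a covariate Stab1 was at 0.82 ± 0.16 (adjusted p = 0.0209, range 1.2e-05 to 0.0675 over 13 alternatives, the call ending under 1) and Ninl at -0.98 ± 0.24 (adjusted p = 0.15, range 0.0265 to 0.215, the call ending under 9). The Ninl call held in 23 of 39 fits that left out 1 library and ended without TRAF6i-HDL replicates 1 to 7 or 10, PBS replicates 2, 3, 6, 8 or 9, mTORi-HDL replicate 7, or S6K1i-HDL replicates 1 or 7. The value nearest 0 was -0.85 ± 0.20 (adjusted p = 0.132), without PBS replicate 3. The macrophage list lost its call without PBS replicate 8 (adjusted p = 0.0565) or 9 (0.11). The efferocytosis list lost it in 6 of these fits (highest adjusted p = 0.111, without PBS replicate 9) and the unfolded protein response list in 7 (highest 0.164, without PBS replicate 7).

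Under mTORi-HDL, Cd28, Fcgr4, Hpse, Galns and Naglu were lower than in PBS, and Ccl9 and Sele higher. Cd28, the costimulatory receptor of T cells, fell to 6.85 ± 3.15 CPM from 25.7 ± 16.4, a log2 fold change of -2.03 ± 0.27 (n = 10 and 10, adjusted p = 8.4e-06, below the PBS mean in 10 of 10 samples). Fcgr4, an activating receptor for IgG, fell by 1.33 ± 0.23 on the log2 scale (adjusted p = 0.0025, 10 of 10). Hpse, the heparanase that cleaves heparan sulfate, fell by 1.18 ± 0.21 (adjusted p = 0.0025, 10 of 10), Galns, a lysosomal sulfatase, by 0.73 ± 0.13 (adjusted p = 0.0025, 10 of 10) and Naglu, a lysosomal glucosaminidase, by 0.85 ± 0.18 (adjusted p = 0.00621, 9 of 10). Ccl9, a chemokine, rose by 0.96 ± 0.18 (adjusted p = 0.00342, 10 of 10) and Sele, the E-selectin of activated endothelium, by 1.38 ± 0.27 (adjusted p = 0.00472, 10 of 10). In all, 65 genes were higher and 106 lower, with 1831 at an unadjusted p under 0.05.

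The foam cell and lipid-associated macrophage list had 6 of 24 members lower and 0 higher, or 9 lower and 1 higher when adjusted over the list alone. Its median was -0.36 (adjusted p = 2.05e-05, 0.531 with an estimated correlation). Acp5, the tartrate-resistant acid phosphatase, fell by 0.97 ± 0.20 (adjusted p = 0.00704, below the PBS mean in 10 of 10 samples), and Gpnmb, a glycoprotein of lipid-laden macrophages, fell by 1.13 ± 0.27 (adjusted p = 0.018, 10 of 10). The Gpnmb call ended without PBS replicate 3 (-1.04 ± 0.28, adjusted p = 0.0518) or 4 (-0.91 ± 0.26, adjusted p = 0.0755). The lysosome and TFEB target list had 4 of 46 members lower, or 7 over the list alone, Naglu among them. The list median was -0.20 (adjusted p = 2.05e-05, 0.357 with an estimated correlation). The list of oxidative phosphorylation had 1 of 73 members lower, or 5 over the list alone. Its median was -0.31 (adjusted p = 3.14e-08, 0.342 with an estimated correlation). The proliferation list had Cdk1, the mitotic kinase, as its 1 lower member of 30, at -1.68 ± 0.35 (adjusted p = 0.00675, 10 of 10), or 4 lower when adjusted over the list alone. For the list as a whole the median was -0.49 (adjusted p = 2.05e-05, and adjusted p = 0.342 with an estimated correlation). Its mean log2 CPM was 2.42 to 2.64 in mTORi-HDL replicates 1 to 4 and 3.12 to 3.55 in replicates 5 to 10, against 3.32 ± 0.51 in PBS. Sepp1, the selenoprotein P gene of resident-like macrophages, fell by 1.48 ± 0.27 (adjusted p = 0.0025, 10 of 10), and Ms4a6c, a membrane protein of myeloid cells, by 1.25 ± 0.23 (adjusted p = 0.0025, 10 of 10). Psap, which encodes the saposins that help degrade sphingolipids, was at -0.96 ± 0.27 and did not pass (adjusted p = 0.0504, range 0.00511 to 0.61 over 13 alternatives).

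Among lists that moved upward, monocyte recruitment and adhesion had 3 of 25 members higher, or 5 higher and 2 lower when adjusted over the list alone. The whole list had a median of 0.17 (adjusted p = 0.00782, and adjusted p = 0.342 with an estimated correlation). The higher members were Sele, named above, Itgam, the integrin chain CD11b, at 0.71 ± 0.15 (adjusted p = 0.00718, 10 of 10), and Cx3cl1, a membrane-bound chemokine, at 0.84 ± 0.20 (adjusted p = 0.0155, 10 of 10). The endothelial marker list had 2 of 19 members higher and 1 lower, or 6 higher and 1 lower when adjusted over the list alone. Its median was 0.46 (adjusted p = 0.000112, and adjusted p = 0.342 with an estimated correlation). Flt1, a receptor for VEGF, rose by 0.74 ± 0.16 (adjusted p = 0.0109, 10 of 10). The focal adhesion and actin list had 2 of 41 members higher, or 4 over the list alone. Its median was 0.24 (adjusted p = 0.00231, 0.342 with an estimated correlation). Flna, an actin crosslinker, was at 0.68 ± 0.16 (adjusted p = 0.0142, 9 of 10). The immediate early list had 0 of 23 members past the threshold, or 3 higher over the list alone. Its median was 0.46 (adjusted p = 0.000119, 0.342 with an estimated correlation). By fry, these 4 lists moved one way (adjusted p = 0.0274, 0.019, 0.0035 and 0.0274 in the order given here). Bmp6, a growth factor, rose by 1.25 ± 0.24 (adjusted p = 0.00313, 10 of 10), and Rps10, a ribosomal protein, by 0.91 ± 0.17 (adjusted p = 0.0025, 9 of 10).

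The interferon-stimulated list had 0 of 30 members past the threshold, also when adjusted over the list alone. Over all members the median was -0.26 (adjusted p = 0.0111, and adjusted p = 0.666 with an estimated correlation), and its call ended without PBS replicate 2 (adjusted p = 0.165) or mTORi-HDL replicate 5 (0.0665). A further 6 lists passed by a narrower margin, and each lost its call in 6 to 25 of the 39 fits that left out 1 library. Sphingolipid degradation was among them (0 higher and 2 lower of 25, 5 lower over the list alone, adjusted p = 0.0368, and adjusted p = 0.457 with an estimated correlation, highest without PBS replicate 2 at 0.083). Ribosomal proteins were as well (1 higher of 76, 6 over the list alone, adjusted p = 0.0361, and adjusted p = 0.874 with an estimated correlation, highest without mTORi-HDL replicate 7 at 0.21). The alternative activation list was another (0 higher and 3 lower of 12, 2 higher and 5 lower over the list alone, adjusted p = 0.0461, and adjusted p = 0.342 with an estimated correlation, highest without mTORi-HDL replicate 9 at 0.0838). So was efferocytosis (2 lower of 27, 1 higher and 9 lower over the list alone, adjusted p = 0.0461, and adjusted p = 0.613 with an estimated correlation, highest without mTORi-HDL replicate 5 at 0.229), and so were smooth muscle markers (0 of 15, 1 higher over the list alone, adjusted p = 0.0197, and adjusted p = 0.664 with an estimated correlation, highest without PBS replicate 1 at 0.101). The last was the macrophage marker list (1 higher and 1 lower of 24, 2 higher and 8 lower over the list alone, adjusted p = 0.047, and adjusted p = 0.685 with an estimated correlation, highest without mTORi-HDL replicate 8 at 0.251). The macrophage members past the threshold were Itgam and Aif1, an actin-binding protein of macrophages, at -1.01 ± 0.22 (adjusted p = 0.00931, 10 of 10), whose call ended without PBS replicate 2 (-0.67 ± 0.20, adjusted p = 0.0761).

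The Rn45s share was 23.1% ± 7.81 in mTORi-HDL and 13% ± 10.9 in PBS, and with it as a covariate 21 genes passed, 13 of them among the 171. Cd28 (-2.0 ± 0.32), Fcgr4 (-0.99 ± 0.23), Hpse (-1.14 ± 0.23), Galns (-0.72 ± 0.14), Naglu (-0.81 ± 0.18), Ccl9 (0.94 ± 0.21) and Sele (1.35 ± 0.31) stayed past the threshold there. Those no longer passing were Sepp1 (-0.78 ± 0.25), Ms4a6c (-0.73 ± 0.20), Acp5 (-0.66 ± 0.23), Gpnmb (-1.03 ± 0.32), Cdk1 (-1.53 ± 0.38), Aif1 (-0.86 ± 0.24), Itgam (0.53 ± 0.15), Cx3cl1 (0.69 ± 0.21), Flt1 (0.60 ± 0.17), Flna (0.35 ± 0.13), Bmp6 (0.78 ± 0.21) and Rps10 (0.65 ± 0.16). In the same fit the foam cell list (median -0.23, adjusted p = 0.0809, range 1.99e-10 to 0.0809 over 11 alternatives) and oxidative phosphorylation (-0.10, adjusted p = 0.0641, range 3.35e-10 to 0.0641) lost their calls. Alternative activation (-0.18, between -0.47 and 0.23 over the alternatives, adjusted p = 0.29, range 0.00535 to 0.29), macrophage markers (-0.16, adjusted p = 0.742, range 0.000436 to 0.742), efferocytosis (-0.05, adjusted p = 0.0546, range 0.00115 to 0.152) and smooth muscle markers (0.30, adjusted p = 0.462, range 0.00517 to 0.462) did as well. The ribosomal protein median went from 0.05 to 0.27 (adjusted p = 6.1e-21, range 6.1e-21 to 0.132).

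The count of 171 genes moved with single libraries. It was 79 without PBS replicate 3, 73 without 4, 91 without 5, 76 without 6, 435 without 8 and 356 without 10, 291 without TRAF6i-HDL replicate 8, 361 without mTORi-HDL replicate 5 and 95 without mTORi-HDL replicate 8.

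The series lists mTORi-HDL replicates 1 to 4 apart from replicates 5 to 10. Taken as separate groups, 33 genes and 15 lists differed between these sets, while 117 and 160 genes passed against PBS. At an estimated correlation 3 lists differed between the sets. Within the 10 mTORi-HDL samples alone this division called 70 genes, and the other divisions into 4 and 6 samples, of 210 in all, called at most 18. The proliferation list passed against PBS in replicates 1 to 4 (median -1.32, adjusted p = 1.08e-19, and adjusted p = 0.00646 with an estimated correlation) and not in 5 to 10 (-0.17, adjusted p = 0.11). The foam cell (-0.59), lysosome (-0.29) and interferon-stimulated (-0.74) lists passed in replicates 5 to 10 (adjusted p = 3.62e-08 each, and adjusted p = 0.278, 0.273 and 0.278 with an estimated correlation) and not in 1 to 4, where the medians were -0.23 (adjusted p = 0.445), -0.10 (0.322) and 0.15 (0.445). The oxidative phosphorylation list passed in both sets (-0.26, adjusted p = 1.85e-05, and -0.32, adjusted p = 3.62e-08) and in neither with an estimated correlation (adjusted p = 0.602 and 0.278). NF-kB target genes, which did not pass in the group as a whole, passed in replicates 1 to 4 at the preset correlation (0.38, adjusted p = 7.16e-06) and not at an estimated one (adjusted p = 0.0623).

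**Figure D2:**
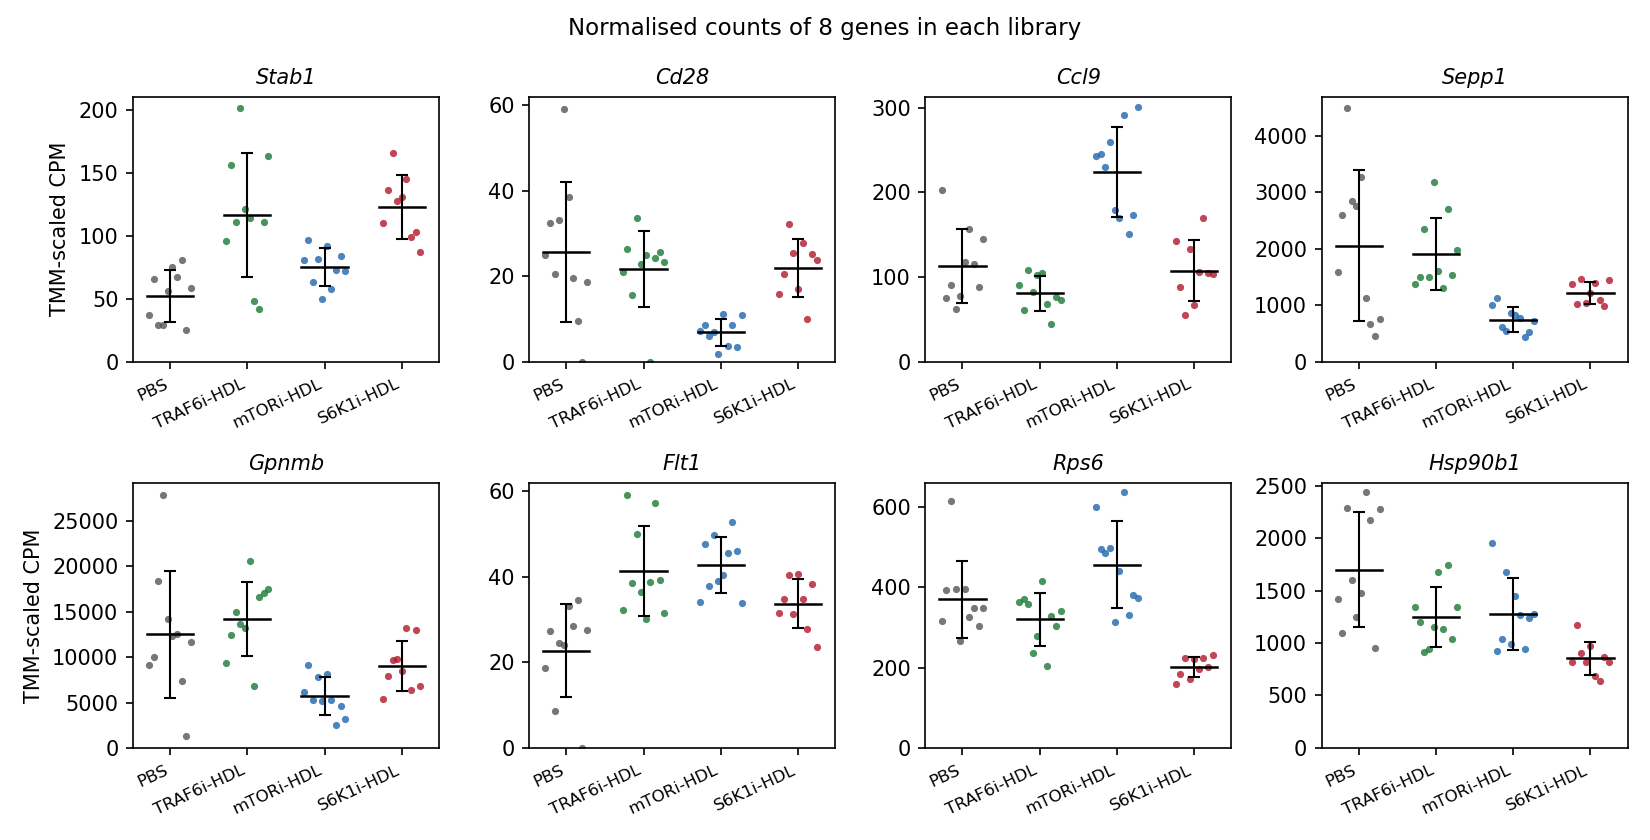
TMM-scaled CPM of 8 genes in each library, with the mean and standard deviation of each group. Cd28 lies at 6.85 ± 3.15 CPM in mTORi-HDL and 25.7 ± 16.4 in PBS, Ccl9 at 224 ± 53.0 and 113 ± 44.1, and Rps6 at 202 ± 25.5 in S6K1i-HDL against 371 ± 95.7 in PBS.

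Under S6K1i-HDL, Rps6, Rps12, Rpl17, Atp5l, Cox7c, Sdf2l1 and Hsp90b1 were lower than in PBS, and Stab1, Cx3cl1 and Nr1d1 higher. Rps6, the ribosomal protein that S6K1 phosphorylates, fell to 202 ± 25.5 CPM from 371 ± 95.7, a log2 fold change of -0.87 ± 0.15 (n = 9 and 10, adjusted p = 0.000217, below the PBS mean in 9 of 9 samples). Of 76 ribosomal protein genes tested, 47 fell, 0 rose and 29 did not pass, or 60 fell and 1 rose when adjusted over the list alone. The list median was -0.52 (adjusted p = 1.31e-29, and adjusted p = 0.281 with an estimated correlation). Rps12 fell by 1.05 ± 0.17 and Rpl17 by 1.06 ± 0.18 (adjusted p = 0.000217 each, 9 of 9). Of 73 genes of oxidative phosphorylation, 32 fell and 0 rose, or 39 fell when adjusted over the list alone. Across the list the median was -0.49 (adjusted p = 6.4e-15, and adjusted p = 0.281 with an estimated correlation). Atp5l, a subunit of ATP synthase, fell by 1.07 ± 0.18 (adjusted p = 0.000239, 9 of 9) and Cox7c, a subunit of cytochrome oxidase, by 1.16 ± 0.24 (adjusted p = 0.00204, 9 of 9). By fry both lists moved one way (adjusted p = 0.00125 each). In all, 568 genes were higher and 674 lower, with 2815 at an unadjusted p under 0.05, and with DESeq2 size factors 744 were higher and 533 lower.

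The unfolded protein response list had 9 of 21 members lower and 1 higher, or 10 lower and 2 higher when adjusted over the list alone. For the list as a whole the median was -0.34 (adjusted p = 0.000227, and adjusted p = 0.615 with an estimated correlation, fry adjusted p = 0.0107). Sdf2l1 fell by 1.08 ± 0.18 (adjusted p = 0.000239, 9 of 9), Hsp90b1, the chaperone GRP94, by 0.99 ± 0.17 (adjusted p = 0.000271, 9 of 9) and Manf, a stress-induced secreted factor, by 0.99 ± 0.17 (adjusted p = 0.000255, 9 of 9). The foam cell list had 6 of 24 members lower, or 10 when adjusted over the list alone. The whole list had a median of -0.47 (adjusted p = 0.00073, and adjusted p = 0.906 with an estimated correlation). Fabp5, a fatty acid carrier, was at -1.32 ± 0.24 (adjusted p = 0.000556, 9 of 9) and Cd9, a tetraspanin, at -1.37 ± 0.34 (adjusted p = 0.00737, 9 of 9). Psap fell by 1.25 ± 0.28 (adjusted p = 0.00322, 9 of 9). The oxidative stress list had 5 of 21 members lower, or 6 when adjusted over the list alone. Its median was -0.30 (adjusted p = 0.0066, and adjusted p = 0.906 with an estimated correlation). Its lower members included Sod1, the cytosolic superoxide dismutase, at -0.74 ± 0.14 (adjusted p = 0.000915, 9 of 9). Fth1, the ferritin heavy chain, was at -1.06 ± 0.24 (adjusted p = 0.00297, 9 of 9), and Gsr, glutathione reductase, at -0.73 ± 0.18 (adjusted p = 0.00558, 9 of 9). The proliferation list had 3 of 30 members lower, or 2 when adjusted over the list alone. The median of the list was -0.43 (adjusted p = 0.0082, and adjusted p = 0.906 with an estimated correlation, 0.121 at the preset one without PBS replicate 8). Cdk1 was at -1.46 ± 0.36 (adjusted p = 0.00562, 9 of 9) and Kif23, a kinesin of cell division, at -1.06 ± 0.31 (adjusted p = 0.0207, 9 of 9).

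Smooth muscle markers were the 1 list that moved upward, with 4 of 15 members higher, or 7 higher and 1 lower when adjusted over the list alone. Members had a median of 0.64 (adjusted p = 0.00293, and adjusted p = 0.906 with an estimated correlation). Smtn, a contractile filament protein, rose by 1.47 ± 0.30 (adjusted p = 0.00208, 9 of 9) and Synpo2, an actin-binding protein of muscle, by 1.28 ± 0.32 (adjusted p = 0.00789, 9 of 9). Stab1 rose by 1.13 ± 0.19 (adjusted p = 0.000237, 9 of 9), Cx3cl1 by 1.13 ± 0.20 (adjusted p = 0.000324, 9 of 9) and Nr1d1, the clock repressor REV-ERBα, by 1.11 ± 0.19 (adjusted p = 0.000239, 8 of 9). Ranbp1, a cofactor of nuclear transport, fell by 1.12 ± 0.19 (adjusted p = 0.000217, 9 of 9). Rps6kb1, which encodes S6K1 itself, was at -0.24 ± 0.16 (adjusted p = 0.334) and Mtor at 0.31 ± 0.20 (adjusted p = 0.313).

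The Rn45s share was 37.0% ± 10.3 in S6K1i-HDL and 13% ± 10.9 in PBS. With it as a covariate 38 genes passed, 26 of them among the 1242, and 109 of the 1242 had the opposite sign. Rps6 (-0.72 ± 0.17, adjusted p = 0.0321, range 2.81e-06 to 0.0321 over 13 alternatives), Sdf2l1 (-1.31 ± 0.21, adjusted p = 0.000321, range 1.01e-05 to 0.00101) and Hsp90b1 (-1.05 ± 0.19, adjusted p = 0.00263, range 4.68e-06 to 0.00263) stayed past the threshold. None of the others named passed. Lower genes were at -0.67 ± 0.18 for Rps12, -0.55 ± 0.18 for Rpl17, -0.57 ± 0.17 for Atp5l, -0.27 ± 0.16 for Cox7c, -0.67 ± 0.19 for Manf, -1.10 ± 0.29 for Fabp5, -0.15 ± 0.24 for Cd9 and -0.31 ± 0.26 for Psap. A further 6 were at -0.53 ± 0.16 for Sod1, -0.87 ± 0.28 for Fth1, -0.40 ± 0.19 for Gsr, -1.24 ± 0.43 for Cdk1, -0.74 ± 0.20 for Ranbp1 and -1.02 ± 0.36 for Kif23. Higher genes were at 0.54 ± 0.26 for Smtn, 0.89 ± 0.37 for Synpo2, 0.47 ± 0.19 for Stab1, 0.88 ± 0.24 for Cx3cl1 and 0.80 ± 0.22 for Nr1d1. List medians in that fit were -0.24 for ribosomal proteins, -0.15 for oxidative phosphorylation, -0.40 for the unfolded protein response and -0.53 for proliferation, all past the threshold at the preset correlation. They were -0.05 for foam cell genes (adjusted p = 0.861, range 1.05e-06 to 0.861 over 11 alternatives), -0.13 for oxidative stress (0.0969, range 6.22e-05 to 0.0969) and 0.22 for smooth muscle (0.505, range 0.000368 to 0.505), which lost their calls. With GC content and length offsets 495 genes passed, and the count of 1242 was 806 without PBS replicate 3 and 790 without S6K1i-HDL replicate 3.

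The series likewise lists S6K1i-HDL replicates 1 to 6 apart from replicates 7 to 9. Taken as separate groups, they had 1408 genes and 1 gene past the threshold against PBS, with 6 and 3 samples. Between the sets 0 genes and 5 lists differed, and at an estimated correlation 0 lists. Within the 9 S6K1i-HDL samples alone this division called 75 genes, and 2 of the other divisions, of 84 in all, called at least as many (highest 658). At the preset correlation ribosomal proteins were lower than in PBS in both sets (median -0.72, adjusted p = 4.54e-41, and -0.29, adjusted p = 5.29e-09), as were oxidative phosphorylation (-0.69, adjusted p = 1.62e-19, and -0.25, adjusted p = 1.58e-05), proliferation (-0.45, adjusted p = 0.0128, and -0.38, adjusted p = 0.00305) and the unfolded protein response (-0.25, adjusted p = 0.00387, and -0.32, adjusted p = 2.17e-06). With an estimated correlation no list passed in either set (lowest adjusted p = 0.0674 and 0.37).

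**Figure D3:**
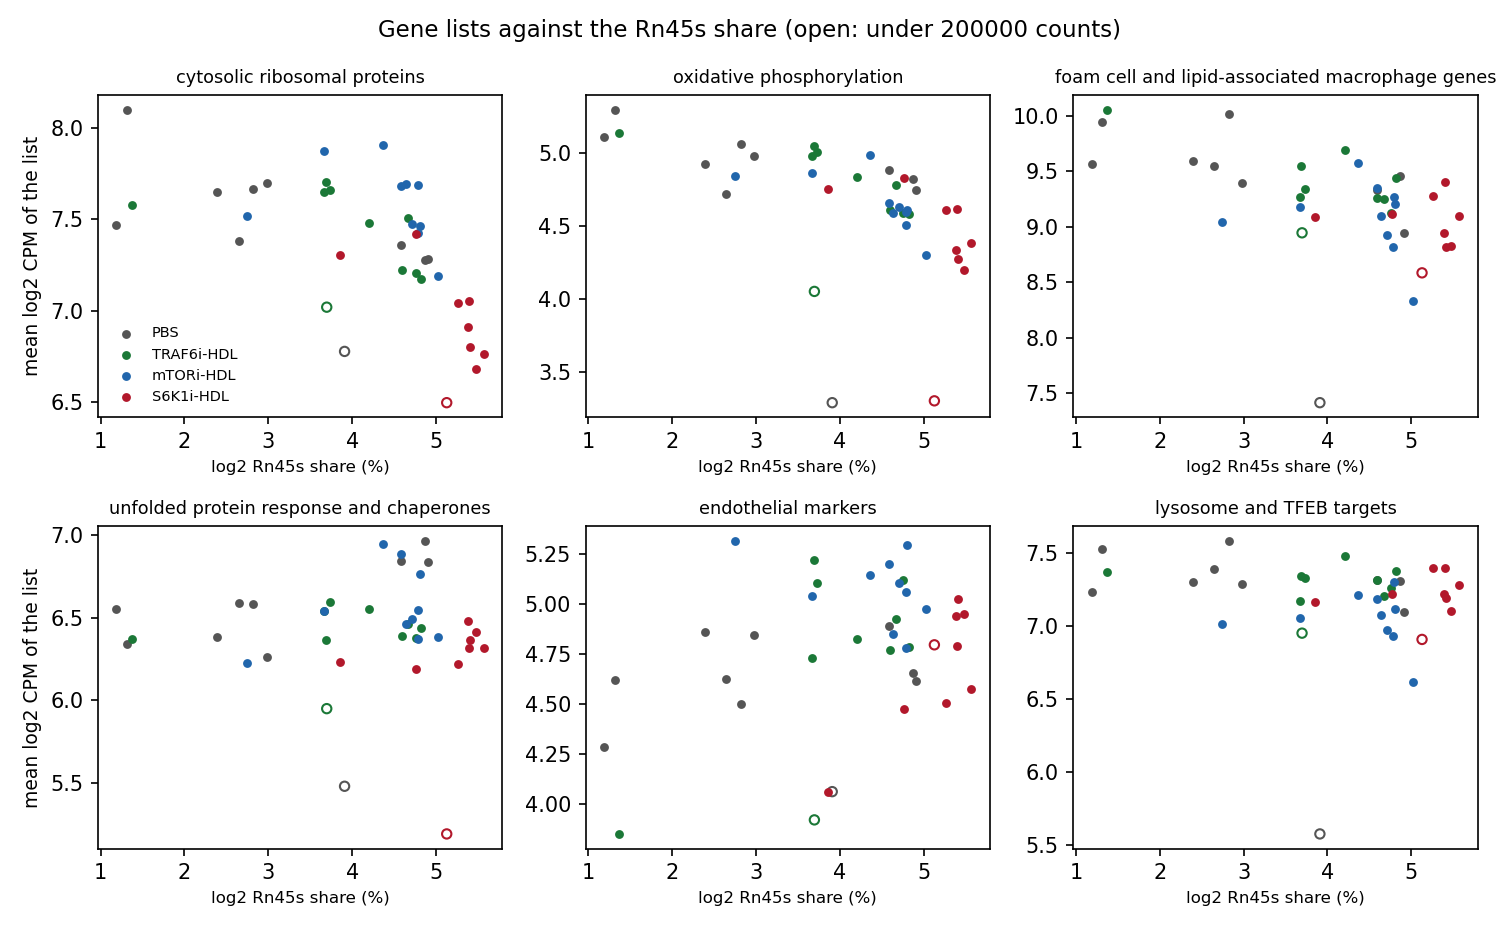
Mean log2 CPM of the members of 6 gene lists in each library against the log2 of the Rn45s share (%), coloured by group, with the 3 libraries under 200000 counts as open circles. From PBS to S6K1i-HDL the median of the ribosomal protein genes differed by -0.52 and that of oxidative phosphorylation by -0.49 on the log2 scale, while the mean share went from 13% to 37.0%.

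Between TRAF6i-HDL and mTORi-HDL, whose Rn45s shares were 17.8% ± 8.31 and 23.1% ± 7.81, Cd4, Cd28, Il18bp and Il10ra were higher under TRAF6i-HDL, and Ccl9, Ereg and Malt1 lower. Cd4, the coreceptor of helper T cells, was at 45.6 ± 13.6 CPM under TRAF6i-HDL and 9.26 ± 6.40 under mTORi-HDL, a log2 difference of 2.31 ± 0.35 (n = 10 and 10, adjusted p = 8.52e-05, above the mTORi-HDL mean in 10 of 10 samples). Cd28 was higher under TRAF6i-HDL by 1.79 ± 0.27 (adjusted p = 5.73e-05, 9 of 10), Il18bp, which binds interleukin 18, by 1.57 ± 0.23 (adjusted p = 6.24e-05, 10 of 10), and Il10ra, a chain of the interleukin 10 receptor, by 0.96 ± 0.15 (adjusted p = 8.52e-05, 10 of 10). Lower under TRAF6i-HDL were Ccl9 at -1.43 ± 0.18 (adjusted p = 4.39e-06, 10 of 10), Ereg, an EGF receptor ligand, at -1.66 ± 0.24 (adjusted p = 4.37e-05, 10 of 10), and Malt1, a protease of NF-kB signalling, at -1.05 ± 0.17 (adjusted p = 8.52e-05, 10 of 10). In all, 162 genes were higher under TRAF6i-HDL and 142 lower, with 1735 at an unadjusted p under 0.05. The 7 genes named in this paragraph passed under each of the 13 alternatives and with any 1 library left out. Genes whose call held with any 1 library left out were preferred as examples, so that part is no further support.

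The macrophage marker list had 7 of 24 members higher under TRAF6i-HDL and 1 lower, or 11 and 1 when adjusted over the list alone. Over all members the median was 0.35 (adjusted p = 5.51e-07, and adjusted p = 0.235 with an estimated correlation). C1qc, a chain of complement C1q, was at 1.2 ± 0.27 (adjusted p = 0.00861, 10 of 10) and Aif1 at 1.24 ± 0.22 (adjusted p = 0.000362, 9 of 10). Itgam, the 1 lower member, was at -0.74 ± 0.15 (adjusted p = 0.00224, 10 of 10). The efferocytosis list had 8 of 27 members higher and 1 lower, or 14 and 1 when adjusted over the list alone. The list median was 0.38 (adjusted p = 4.18e-06, and adjusted p = 0.169 with an estimated correlation). Its mean log2 CPM was 7.14 ± 0.28 under TRAF6i-HDL. In mTORi-HDL it was 7.05 ± 0.21 in replicates 1 to 4 and 6.67 ± 0.08 in replicates 5 to 10. Stab2 was at 2.08 ± 0.36 (adjusted p = 0.000362, 9 of 10), Fcgr4 at 1.11 ± 0.23 (adjusted p = 0.00284, 9 of 10), and Thbs1, a matrix glycoprotein and the 1 lower member, at -1.35 ± 0.30 (adjusted p = 0.0072, 10 of 10). The lysosome list had 6 of 46 members higher and 1 lower, or 13 and 2 when adjusted over the list alone. Across the list the median was 0.24 (adjusted p = 1.25e-06, and adjusted p = 0.235 with an estimated correlation). Its mean log2 CPM was 7.28 ± 0.15 under TRAF6i-HDL. In mTORi-HDL it was 7.19 ± 0.09 in replicates 1 to 4 and 6.95 ± 0.18 in replicates 5 to 10. Sphingolipid degradation had 3 of 25 members higher and 1 lower, or 7 and 1 when adjusted over the list alone. For the list as a whole the median was 0.09 (adjusted p = 0.0116, and adjusted p = 0.304 with an estimated correlation). Both hold Glb1, the lysosomal galactosidase, at 0.84 ± 0.17 (adjusted p = 0.0019, 9 of 10).

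The foam cell list had 2 of 24 members higher under TRAF6i-HDL, or 11 higher and 2 lower when adjusted over the list alone. The whole list had a median of 0.38 (adjusted p = 9.24e-06, and adjusted p = 0.304 with an estimated correlation). Its mean log2 CPM was 9.39 ± 0.31 under TRAF6i-HDL. In mTORi-HDL it was 9.32 ± 0.20 in replicates 1 to 4 and 8.92 ± 0.32 in replicates 5 to 10. The 2 members past the threshold were Acp5 at 1.26 ± 0.20 (adjusted p = 0.000102, 10 of 10) and Gpnmb at 1.32 ± 0.27 (adjusted p = 0.00276, 10 of 10). The alternative activation list had 3 of 12 members higher, or 6 higher and 3 lower when adjusted over the list alone. Its median was 0.61 (adjusted p = 0.0049, and adjusted p = 0.169 with an estimated correlation). Sepp1, a member, was at 1.36 ± 0.27 (adjusted p = 0.00207, 10 of 10). The list lost its call under 1 of 11 alternatives (range 0.000693 to 0.142). The T and NK cell list had Cd4 as its 1 higher member of 5, also when adjusted over the list alone. The median of the list was 0.91 (adjusted p = 0.00751, and adjusted p = 0.235 with an estimated correlation). The immediate early list had 3 of 23 members lower, or 7 lower and 1 higher when adjusted over the list alone. Members had a median of -0.56 (adjusted p = 9.24e-06, and adjusted p = 0.235 with an estimated correlation). Egr2, a growth-response transcription factor, was at -0.85 ± 0.17 (adjusted p = 0.00207, 10 of 10). The focal adhesion list had 4 of 41 members lower, or 5 lower and 1 higher when adjusted over the list alone. Over all members the median was -0.14 (adjusted p = 0.00194, and adjusted p = 0.228 with an estimated correlation). Rhoa, a small GTPase, was at -0.54 ± 0.12 (adjusted p = 0.00851, 10 of 10). Monocyte recruitment had 1 of 25 members higher and 3 lower, or 2 and 3 when adjusted over the list alone. The list median was -0.17 (adjusted p = 0.04, and adjusted p = 0.309 with an estimated correlation). Sele was at -1.18 ± 0.26 (adjusted p = 0.0067, 10 of 10). The list lost its call under 5 of 11 alternatives (range 0.0066 to 0.122) and in 11 of 39 fits that left out 1 library (highest adjusted p = 0.0946, without mTORi-HDL replicate 4). Slc7a11, the cystine transporter, was at -1.80 ± 0.36 (adjusted p = 0.00303, 10 of 10) and Lox, the collagen crosslinking oxidase, at -0.84 ± 0.18 (adjusted p = 0.00362, 10 of 10).

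In a further 7 lists that passed at the preset correlation, at most 2 members passed over all genes. With medians under TRAF6i-HDL against mTORi-HDL, they were cholesterol efflux (0.15, 0 of 16, 2 higher over the list alone, adjusted p = 0.0148, and adjusted p = 0.304 with an estimated correlation) and ribosomal proteins (-0.12, 2 lower of 76, 2 over the list alone, adjusted p = 6.29e-05, and adjusted p = 0.561 with an estimated correlation). Oxidative phosphorylation was there too (0.19, 1 higher of 73, 1 over the list alone, adjusted p = 6.95e-05, and adjusted p = 0.316 with an estimated correlation). So was proliferation (0.33, 0 of 30, 4 higher over the list alone, adjusted p = 0.000183, and adjusted p = 0.304 with an estimated correlation). Its mean log2 CPM was 3.24 ± 0.55 under TRAF6i-HDL, 2.55 ± 0.10 in mTORi-HDL replicates 1 to 4 and 3.37 ± 0.17 in replicates 5 to 10. Interferon-stimulated genes followed (0.57, 0 of 30, 0 over the list alone, adjusted p = 4.95e-06, and adjusted p = 0.304 with an estimated correlation), as did antigen presentation (0.34, 0 of 19, 0 over the list alone, adjusted p = 0.00194, and adjusted p = 0.316 with an estimated correlation). The mean log2 CPM of the interferon-stimulated list was 4.05 ± 0.54 under TRAF6i-HDL, 4.12 ± 0.57 in mTORi-HDL replicates 1 to 4 and 3.25 ± 0.34 in replicates 5 to 10. The last were endothelial markers (-0.19, 0 of 19, 0 over the list alone, adjusted p = 0.0164, and adjusted p = 0.304 with an estimated correlation, 0.0512 at the preset one without mTORi-HDL replicate 5). By fry, 10 lists moved one way, 8 of them among these 17. The smallest adjusted p, 0.00563, was for focal adhesion, alternative activation and efferocytosis. With DESeq2 size factors 64.8% of the genes past the threshold were higher under TRAF6i-HDL, and with GC content and length offsets 69.0%, against 53.3% with TMM factors.

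Between TRAF6i-HDL and S6K1i-HDL, whose Rn45s shares were 17.8% ± 8.31 and 37.0% ± 10.3, Rpl23, Rpl36a, Ndufa1, Sod1, Fth1 and Txnrd1 were higher under TRAF6i-HDL, and Itpripl2 lower. Of 76 ribosomal protein genes, 22 were higher and 0 lower, or 53 and 0 when adjusted over the list alone. Across the list the median was 0.43 (adjusted p = 1.37e-36, and adjusted p = 0.188 with an estimated correlation). Rpl23 was at 0.99 ± 0.19 (n = 10 and 9, adjusted p = 0.0032, above the S6K1i-HDL mean in 9 of 10 samples) and Rpl36a at 0.91 ± 0.17 (adjusted p = 0.00284, 10 of 10). Of 73 genes of oxidative phosphorylation, 6 were higher and 0 lower, or 24 and 0 when adjusted over the list alone. For the list as a whole the median was 0.35 (adjusted p = 3.4e-16, and adjusted p = 0.188 with an estimated correlation). Its mean log2 CPM was 4.76 ± 0.32 under TRAF6i-HDL. In S6K1i-HDL it was 4.19 ± 0.45 in replicates 1 to 6 and 4.73 ± 0.11 in replicates 7 to 9. Ndufa1, a subunit of complex I, was at 0.97 ± 0.21 (adjusted p = 0.0111, 10 of 10). The oxidative stress list had 4 of 21 members higher, or 5 when adjusted over the list alone. The whole list had a median of 0.23 (adjusted p = 5.67e-05, and adjusted p = 0.384 with an estimated correlation). Sod1 was at 0.84 ± 0.14 (adjusted p = 0.00122, 10 of 10), Fth1 at 1.11 ± 0.24 (adjusted p = 0.00968, 10 of 10) and Txnrd1, a thioredoxin reductase, at 0.74 ± 0.15 (adjusted p = 0.00905, 10 of 10). By fry these 3 lists moved one way (adjusted p = 0.00791, 0.00791 and 0.0369). The macrophage list had 2 of 24 members higher and 1 lower, or 5 and 1 when adjusted over the list alone. Its median was 0.27 (adjusted p = 0.000784, and adjusted p = 0.57 with an estimated correlation). Cd14, a receptor for bacterial lipids, was at 0.96 ± 0.20 (adjusted p = 0.00965, 9 of 10). Lower under TRAF6i-HDL was Itpripl2 at -1.18 ± 0.18 (adjusted p = 0.000142, 10 of 10), and in all 125 genes were higher and 41 lower, with 1642 at an unadjusted p under 0.05.

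The foam cell list had 2 of 24 members higher, or 5 when adjusted over the list alone (median 0.42, adjusted p = 6.82e-06, and adjusted p = 0.57 with an estimated correlation). Proliferation had 0 of 30, also over the list alone (median 0.30, adjusted p = 0.00793, and adjusted p = 0.575 with an estimated correlation). The unfolded protein response had 1 of 21 higher, or 4 over the list alone (median 0.17, adjusted p = 0.0187, and adjusted p = 0.57 with an estimated correlation, 0.0535 at the preset one without S6K1i-HDL replicate 7). With the Rn45s share as a covariate 30 genes passed, 20 of them among the 166. Itpripl2 (-1.10 ± 0.19), Sod1 (0.73 ± 0.14), Fth1 (1.01 ± 0.24), Rpl23 (0.72 ± 0.18) and Rpl36a (0.65 ± 0.15) passed there. Txnrd1 (0.44 ± 0.14), Cd14 (0.75 ± 0.20) and Ndufa1 (0.55 ± 0.18) did not. Neither did the foam cell list (median 0.11, adjusted p = 0.0934, range 6.79e-09 to 0.0934 over 11 alternatives) and the macrophage list (median 0.17, adjusted p = 0.0934, range 1.14e-06 to 0.0934). The count of 166 was 73, 259, 99 and 63 without TRAF6i-HDL replicates 3, 4, 6 and 8, and 56, 68, 66, 66, 76 and 257 without S6K1i-HDL replicates 2, 3, 4, 5, 6 and 9.

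Between mTORi-HDL and S6K1i-HDL, whose Rn45s shares were 23.1% ± 7.81 and 37.0% ± 10.3, Rps6, Rps3a1, Dusp1, Klf2 and Emcn were higher under mTORi-HDL, and Cd4, Cd28 and Stat2 lower. Rps6 was at 456 ± 108 CPM under mTORi-HDL and 202 ± 25.5 under S6K1i-HDL, a log2 difference of 1.16 ± 0.14 (n = 10 and 9, adjusted p = 7.71e-07, above the S6K1i-HDL mean in 10 of 10 samples). Of 76 ribosomal protein genes, 50 were higher and 0 lower, or 64 and 0 when adjusted over the list alone. The median of the list was 0.58 (adjusted p = 5.87e-52, and adjusted p = 0.0574 with an estimated correlation). Rps3a1 was at 1.08 ± 0.14 (adjusted p = 1.01e-06, 10 of 10), Rpl5 at 1.14 ± 0.16 (adjusted p = 5.19e-06, 10 of 10) and Eef1b2, an elongation factor subunit, at 1.28 ± 0.17 (adjusted p = 1.01e-06, 10 of 10). The immediate early list had 7 of 23 members higher and 0 lower, or 8 when adjusted over the list alone. Members had a median of 0.53 (adjusted p = 1.63e-06, and adjusted p = 0.192 with an estimated correlation). Dusp1, a phosphatase of MAP kinases, was at 2.55 ± 0.43 (adjusted p = 0.000271, 10 of 10), and the transcription factors Klf2 at 1.46 ± 0.23 (adjusted p = 1.94e-05, 10 of 10) and Klf4 at 0.91 ± 0.18 (adjusted p = 0.000514, 10 of 10). In all, 364 genes were higher under mTORi-HDL and 279 lower, with 2170 at an unadjusted p under 0.05, and with DESeq2 size factors 40.6% of those past the threshold were higher, against 56.6% with TMM factors.

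The endothelial list had 5 of 19 members higher and 0 lower, or 8 when adjusted over the list alone. Over all members the median was 0.36 (adjusted p = 2.73e-05, and adjusted p = 0.192 with an estimated correlation). Emcn, an endothelial sialomucin, was at 0.93 ± 0.17 (adjusted p = 0.000376, 10 of 10) and Cdh5, the VE-cadherin of endothelial junctions, at 0.91 ± 0.17 (adjusted p = 0.000397, 10 of 10). The unfolded protein response list had 6 of 21 members higher and 1 lower, or 8 and 1 when adjusted over the list alone. The list median was 0.14 (adjusted p = 0.000467, and adjusted p = 0.363 with an estimated correlation). Hspa5, the chaperone BiP, was at 0.85 ± 0.19 (adjusted p = 0.00267, 10 of 10). The oxidative stress list had 8 of 21 members higher and 0 lower, or 10 when adjusted over the list alone. Across the list the median was 0.22 (adjusted p = 0.000467, and adjusted p = 0.363 with an estimated correlation). Slc7a11 was at 1.60 ± 0.35 (adjusted p = 0.00389, 9 of 10). The interferon-stimulated list had 3 of 30 members lower, or 10 when adjusted over the list alone. For the list as a whole the median was -0.69 (adjusted p = 2.13e-07, and adjusted p = 0.363 with an estimated correlation). Its mean log2 CPM was 4.12 ± 0.57 in mTORi-HDL replicates 1 to 4 and 3.25 ± 0.34 in replicates 5 to 10, against 4.24 ± 0.39 in S6K1i-HDL. Stat2, a transcription factor of interferon signalling, was at -0.90 ± 0.18 (adjusted p = 0.000682, 10 of 10) and Oas2, an antiviral synthetase, at -1.35 ± 0.31 (adjusted p = 0.00523, 10 of 10). The T and NK cell list had Cd4 as its 1 lower member of 5, at -2.10 ± 0.34 (adjusted p = 0.000141, 10 of 10), or 4 when adjusted over the list alone. The whole list had a median of -1.33 (adjusted p = 0.0154, and adjusted p = 0.363 with an estimated correlation). Cd28, which is not in that list, was at -1.72 ± 0.27 (adjusted p = 1.94e-05, 10 of 10).

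The efferocytosis list had 5 of 27 members lower, or 8 lower and 1 higher over the list alone. Its median was -0.24 (adjusted p = 0.00425, 0.392 with an estimated correlation). In mTORi-HDL its mean log2 CPM was 7.05 ± 0.21 in replicates 1 to 4 and 6.67 ± 0.08 in replicates 5 to 10. In S6K1i-HDL it was 7.10 ± 0.20. C1qa, a chain of complement C1q, was at -1.23 ± 0.31 (adjusted p = 0.0102, 10 of 10) and Stab1 at -0.72 ± 0.18 (adjusted p = 0.00883, 10 of 10). The lysosome list had 4 of 46 members lower, or 10 lower and 2 higher over the list alone. Its median was -0.18 (adjusted p = 0.00425, 0.577 with an estimated correlation, 0.0585 at the preset one without mTORi-HDL replicate 8). Its mean log2 CPM was 7.19 in mTORi-HDL replicates 1 to 4, 6.95 in 5 to 10 and 7.21 in S6K1i-HDL. Naglu was at -0.96 ± 0.17 (adjusted p = 0.000241, 10 of 10). Oxidative phosphorylation had 4 of 73 members higher, or 5 over the list alone (median 0.22, adjusted p = 0.000467, 0.577 with an estimated correlation). Its mean log2 CPM was 4.66 ± 0.20 in mTORi-HDL. In S6K1i-HDL it was 4.19 ± 0.45 in replicates 1 to 6 and 4.73 ± 0.11 in replicates 7 to 9, which were thus not lower. Cholesterol efflux had 1 of 16 lower, also when adjusted over the list alone (median -0.24, adjusted p = 0.0182, and adjusted p = 0.515 with an estimated correlation, 0.0585 at the preset one without mTORi-HDL replicate 8). With the Rn45s share as a covariate these last 2 lost their calls (median 0.07, adjusted p = 0.321, range 1.6e-05 to 0.374 over 11 alternatives, and -0.14, adjusted p = 0.0547, range 0.0077 to 0.0793). Mmp12, the macrophage elastase, was at 1.69 ± 0.36 (adjusted p = 0.00272, 10 of 10), Hilpda, a lipid droplet protein, at 1.70 ± 0.24 (adjusted p = 4.39e-06, 10 of 10), and Txnip, a thioredoxin inhibitor, at -1.19 ± 0.30 (adjusted p = 0.0102, 10 of 10). By fry, 8 of the 11 lists moved one way, the ribosomal proteins with an adjusted p of 7.86e-05.

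The 3 comparisons with PBS share their 10 control samples, which by itself makes their fold changes alike. Across 10411 genes, which are not independent replicates, the log2 fold changes of mTORi-HDL and S6K1i-HDL correlated with r = 0.550 (covariance 0.0914), where simulated unchanged groups sharing the controls gave 0.556 (covariance 0.0340). With the PBS samples split into sets of 5, so that no control was shared, r was 0.232 ± 0.0640 over 100 splits (covariance 0.0483). In these comparisons 25 genes were higher in both and 35 lower in both, where 3.55 and 6.86 are expected from the counts alone, and 0 moved in opposite directions. Split controls gave a median overlap of 0 genes (range 0 to 15). The simulated 0 is no baseline, as those groups were unchanged. Mean Rn45s shares were higher in mTORi-HDL (23.1%) and S6K1i-HDL (37.0%) than in PBS (13%). Whether this adds to the likeness of their fold changes was not tested. For TRAF6i-HDL and S6K1i-HDL, r was 0.607 (covariance 0.0862), simulated 0.531 (0.0342) and with split controls 0.232 ± 0.0845 (0.0435), and Stab1 and Ninl were shared, 1 higher with 0.0546 expected and 1 lower with 0.0647 expected. With split controls the median overlap of this pair was 0 genes (range 0 to 4). For TRAF6i-HDL and mTORi-HDL, r was 0.442 (covariance 0.0524), simulated 0.548 (0.0341) and with split controls 0.0577 ± 0.105 (0.00790). By edgeR 0 genes were shared by that pair, with 0.00624 higher and 0.0102 lower expected, and the comparisons had 1158 and 1831 genes at an unadjusted p under 0.05. Of the tools run, DESeq2 called 49 and 407 genes in these comparisons and limma-voom 1 and 368. No gene passed in the same direction under all 3 inhibitors.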

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

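The tests on the Rn45s share, the GC content and length of transcripts and the share of macrophages for gene lists, and on samples that the series lists apart within a group, were chosen after the results were seen, as were leaving out the 3 libraries under 200000 counts in the tests of list means and the flags on CPM values, while the tests of breadth and the splits of samples were planned. In groups of 9 or 10 samples, the highest or lowest sample stood apart from its neighbour by more than the 95% limit of Dixon's test in 55 of 376 sets of values, where chance gives 18.8. Of these, 51 concern named genes and 4 library measures. The gene test was first run on log2 CPM, which gave 86 flags over 352 sets. CPM was used after both had been seen.

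S6K1i-HDL replicate 1 held 118527 counts in genes (other samples of its group 5024656 ± 962383) and 8270 detected genes. It stood apart in Naglu (15.8 CPM), Prg4 (1115), Il10ra (15.8), Slc7a11 (87.0), Hilpda (39.5), Dusp1 (166) and Oas2 (94.9), and was listed at 0 for Kif23 and Klf2, where 3 counts would be 25.3 CPM. PBS replicate 9 had 6679 detected genes, Emr1 at 12.6 CPM, Ereg at 75.8 and Kif23 at 0, where 3 counts would be 59.9 CPM. TRAF6i-HDL replicate 7 stood apart in Sdf2l1 and Cdh5 (9.68 CPM each).

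TRAF6i-HDL replicate 8 was the highest of its group for Atp5l (328 CPM), Cox7c (358), Cd9 (6894), Prg4 (2088), Txnrd1 (229), Rpl23 (1062), Rpl36a (402), Ndufa1 (72.5), Dusp1 (1084) and Mmp12 (12575). PBS replicate 3 was the highest for Ninl (73.8 CPM), Rps6 (614), Rpl17 (810), Egr2 (61.8), Rpl36a (354) and Rpl5 (582) and the lowest for Rhoa (158). mTORi-HDL replicate 2 was the highest for Mertk (226 CPM), Emr1 (154), Laptm5 (932) and Stab2 (8.09). mTORi-HDL replicate 5 stood apart in Naglu (31.1 CPM), Bmp6 (22.1) and Rps6kb1 (97.3). mTORi-HDL replicate 7 stood apart in the share of reads with several alignments (11.7%, counting interval 11.7286 to 11.7658) and in Thbs1 (4076 CPM).

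Prg4 in PBS replicate 1 was at 8314 CPM, where the other PBS samples were at 742 ± 433. Further samples apart from their groups were Aif1 in PBS replicate 2 (85.3 CPM), Hpse in PBS replicate 4 (63.4), Ninl in TRAF6i-HDL replicate 9 (15.6) and in S6K1i-HDL replicate 5 (6.01), and Oas2 in TRAF6i-HDL replicate 9 (54.8). The others were Slc7a11 in TRAF6i-HDL replicate 10 (31.5), Cd9 in mTORi-HDL replicate 1 (3509), Traf6 in mTORi-HDL replicate 8 (20.4), Manf in S6K1i-HDL replicate 5 (27.2), Lox in S6K1i-HDL replicate 7 (421) and Ranbp1 in S6K1i-HDL replicate 9 (38.0).

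Without the 3 libraries under 200000 counts the mean of the ribosomal protein genes was lower in S6K1i-HDL than in PBS by 0.55 ± 0.12 on the log2 scale (0.53 ± 0.13 over all samples, which the brackets below give too), beside a rise of the Rn45s share. With the trend on GC content and length removed the difference was -0.26 ± 0.051 (-0.29 ± 0.080), more than 2 standard errors below 0. That argues against this trend alone as the whole cause. With the Rn45s share in the model as well it was -0.19 ± 0.060 (-0.25 ± 0.10). With the other groups' slope on the share and no other correction it was -0.30 ± 0.14 (-0.26 ± 0.16). Over all samples that is within 2 standard errors of 0, so the share, alone or with that trend, is not excluded. S6K1i-HDL replicates 1 to 6 differed from PBS by -0.70 ± 0.12 (-0.68 ± 0.13) and replicates 7 to 9, which the series lists apart, by -0.28 ± 0.14 (-0.21 ± 0.17), so a difference between these sets stays open. An effect of the inhibitor, or of its HDL carrier, which no sample carries alone, may account for part of the difference, as a hypothesis found and tested on the same data, and a batch of libraries that follows the groups stays open, since the labels give no batch.

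Without the same 3 libraries the foam cell list was lower in mTORi-HDL than in PBS by 0.45 ± 0.14 in its mean and the lysosome list by 0.29 ± 0.065, while over all samples these were 0.24 ± 0.20 and 0.11 ± 0.14, each within 2 standard errors of 0. The change of the endothelial list less that of the T and NK cell list was 0.83 ± 0.24 (0.66 ± 0.33 over all samples, barely beyond 2 standard errors), with 5 genes in the latter. These cell types did not move alike, but that cannot decide whether the share of macrophages fell. Over all samples the mean log2 CPM of the macrophage list was 7.95 in mTORi-HDL and 8.07 in PBS (standard deviations 0.30 and 0.57). That PBS mean is pulled down by replicate 9, a library under 200000 counts, at 6.61. The other PBS samples lay between 7.76 and 8.56, and the mTORi-HDL samples between 7.36 and 8.53. These means thus do not show that macrophage markers held their level. A change in endothelial cells themselves stays open too. With the Rn45s share in the model the foam cell difference was -0.25 ± 0.13 (0.00 ± 0.21 over all samples) and the lysosome difference -0.25 ± 0.073 (-0.03 ± 0.16), so the share is excluded for neither list. In mTORi-HDL replicates 1 to 4 they were -0.21 ± 0.17 and -0.14 ± 0.078 (0.00 ± 0.27 and 0.03 ± 0.19 over all samples), and in replicates 5 to 10, which the series lists apart, -0.62 ± 0.15 and -0.39 ± 0.068 (-0.41 ± 0.23 and -0.21 ± 0.17), with more than 2 standard errors between the sets only without the shallow libraries. A trend with the Rn45s share or a difference between these sets of samples, which no label explains, may account for either list. A smaller share of macrophages and an effect of the inhibitor, or of its HDL carrier, stay open.

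Under S6K1i-HDL 1242 genes passed against PBS. With each library thinned to at most 1340382 counts, the PBS median, 973 genes passed, 896 of them among the 1242. PBS libraries under that limit kept their lower depth, so depth was not made equal. With the number of detected genes as a covariate 350 genes passed, 326 of them among the 1242. Depth therefore stays open as part of the cause. Across the 1242 genes, which are not independent replicates, the fold change correlated with the slope on the Rn45s share within 28 libraries of the other groups (all but the 2 under 200000 counts) at r = 0.806 (0.775 to 0.810 with any 1 library left out), where all 10411 genes gave 0.556 and all 30 libraries 0.787 for the 1242, and 1123 (90.4%) had the sign this slope predicts. A trend that moves with the Rn45s share may account for part of the breadth, since the predicted median size was 0.45 and the observed one 0.73. An effect of the inhibitor, or of its HDL carrier, that itself changes the share stays open as well.

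In 100 splits of the samples, the real one included, chance can be excluded for the number of genes in 5 comparisons. The 5 comparisons were mTORi-HDL against PBS (1 split with as many, real 171, highest other 102), S6K1i-HDL against PBS (1, 1242 and 713), TRAF6i-HDL against mTORi-HDL (1, 304 and 5), TRAF6i-HDL against S6K1i-HDL (1, 166 and 40) and mTORi-HDL against S6K1i-HDL (1, 643 and 14). Chance cannot be excluded for TRAF6i-HDL against PBS, where 9 splits gave as many genes (real 2, highest other 365), and a split that calls 365 genes points to a structure of these samples other than their group. The splits that called 713 genes in S6K1i-HDL against PBS and 102 in mTORi-HDL against PBS point to such a structure there too, beside the group. For the number of gene lists, few splits gave as many in mTORi-HDL against PBS (3 splits, real 15, highest other 17) and TRAF6i-HDL against mTORi-HDL (2, 17 and 17). These results are not adjusted over the comparisons, and another split reached 17 lists in each, so chance is not firmly excluded there. It cannot be excluded in TRAF6i-HDL against PBS (79 splits, real 3, highest other 14), S6K1i-HDL against PBS (47, 7 and 17), TRAF6i-HDL against S6K1i-HDL (19, 7 and 13) or mTORi-HDL against S6K1i-HDL (19, 11 and 15). The other splits had a median of 5 lists in TRAF6i-HDL against PBS, 6 in mTORi-HDL against PBS and 6 in S6K1i-HDL against PBS. Between inhibitors the median was 5 for TRAF6i-HDL against mTORi-HDL, 4 for TRAF6i-HDL against S6K1i-HDL and 6 for mTORi-HDL against S6K1i-HDL. Several lists thus pass at the preset correlation without the real grouping. Whether the 14 lists of a split of TRAF6i-HDL and PBS samples come from a structure of the samples was not tested.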

How the results depend on the processing

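The fits with the Rn45s share, with Rn45s left out of the counts, with GC content and length offsets and without the 3 shallowest libraries were chosen after the data were seen, and the others were planned. Of 329 named gene results, 232 were calls, and 105 of these passed in the same direction under all their alternatives. Counts of genes are given for TRAF6i-HDL, mTORi-HDL and S6K1i-HDL against PBS, then TRAF6i-HDL against mTORi-HDL, TRAF6i-HDL against S6K1i-HDL and mTORi-HDL against S6K1i-HDL, beside 2, 171, 1242, 304, 166 and 643, and only where they moved by more than 1.5 times. At these depths, simulated changes of 1.5-fold were recovered for 26.9%, 28.4% and 20.9% of altered genes in the 3 comparisons with PBS. With each library thinned to at most 1340382 counts, genes numbered 2, 152, 973, 222, 116 and 433.

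At an adjusted p under 0.2 the counts were 71, 1169, 2996, 1095, 931 and 1874, as fits a looser threshold. A log2 fold change of at least 1 left 45, 226, 103, 39 and 169 from mTORi-HDL against PBS on, by construction. For the settings that follow the cause was not tested. limma-voom gave 1, 368, 1922, 606, 688 and 1850. The DESeq2 Wald test gave 49 and 407 in the TRAF6i-HDL and mTORi-HDL comparisons with PBS and 348 between TRAF6i-HDL and S6K1i-HDL. In TRAF6i-HDL against PBS, DESeq2 size factors, no low-count filter and leaving out the 3 shallowest libraries gave 1 gene each. The number of detected genes as a covariate gave 1, 82 and 350 against PBS and 66 between TRAF6i-HDL and S6K1i-HDL. The Rn45s share as a covariate gave 1, 21 and 38 against PBS and 30 between TRAF6i-HDL and S6K1i-HDL. The same without the shallow libraries gave 34 for mTORi-HDL and 53 for S6K1i-HDL against PBS, 506 between TRAF6i-HDL and mTORi-HDL and 38 between TRAF6i-HDL and S6K1i-HDL. GC content and length offsets gave 495 in S6K1i-HDL against PBS. With only the 2 groups compared, and so fewer samples, there were 0 (by edgeR, 1158 at an unadjusted p under 0.05 with all groups, 49 by DESeq2 and 1 by limma-voom) and 93 genes in the TRAF6i-HDL and mTORi-HDL comparisons with PBS, 283 between TRAF6i-HDL and S6K1i-HDL and 1094 between mTORi-HDL and S6K1i-HDL. The replicate block gave 84 genes between TRAF6i-HDL and S6K1i-HDL and 5 lists in TRAF6i-HDL against PBS.

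Against 3, 15, 7, 17 and 7 lists, camera with an estimated correlation gave 0 in each comparison, and also 0 against 11 between mTORi-HDL and S6K1i-HDL, while fry gave 0, 4, 3, 10 and 3. The correlations of fold changes with split PBS samples were 0.0577 for TRAF6i-HDL and mTORi-HDL, 0.232 for TRAF6i-HDL and S6K1i-HDL and 0.232 for mTORi-HDL and S6K1i-HDL. Prg4 was at -1.44 in S6K1i-HDL against PBS (adjusted p = 0.0472, range 0.0302 to 0.926) and turned to 0.36 with the Rn45s share as a covariate and 0.20 with that and no shallow libraries. Its call held in 16 of 39 fits that left out 1 library, and without PBS replicate 1 it was at -0.40 (adjusted p = 0.49).

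The share of genes that were higher moved by more than 10 points with DESeq2 size factors in S6K1i-HDL against PBS (58.3% from 45.7%), TRAF6i-HDL against mTORi-HDL (64.8% from 53.3%) and mTORi-HDL against S6K1i-HDL (40.6% from 56.6%). It did so with GC content and length offsets in mTORi-HDL against PBS (21.6% from 38.0%), S6K1i-HDL against PBS (35.4% from 45.7%) and TRAF6i-HDL against mTORi-HDL (69.0% from 53.3%). With the number of detected genes as a covariate it was 18.3% in mTORi-HDL against PBS, 28.9% in S6K1i-HDL against PBS and 87.9% (from 75.3%) in TRAF6i-HDL against S6K1i-HDL. The Rn45s share as a covariate without the shallow libraries gave 23.5% and 32.1% in the mTORi-HDL and S6K1i-HDL comparisons with PBS. The DESeq2 Wald test gave 57.0% in S6K1i-HDL against PBS, 63.8% in TRAF6i-HDL against mTORi-HDL and 39.8% in mTORi-HDL against S6K1i-HDL. Between TRAF6i-HDL and S6K1i-HDL the share was 64.3% with only the 2 groups, 58.1% with limma-voom and 61.7% at an adjusted p under 0.2, a threshold that gave 51.6% in mTORi-HDL against PBS. TRAF6i-HDL against PBS, with 2 genes, is left out here.

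With 1 library left out, genes numbered 1 to 25, 73 to 435, 790 to 1496, 208 to 388, 56 to 259 and 463 to 824, and lists 0 to 8, 10 to 16, 6 to 8, 16 to 18, 6 to 9 and 9 to 12. In TRAF6i-HDL against PBS there were 25 genes without TRAF6i-HDL replicate 8 and 4 without mTORi-HDL replicate 5, and 1 without any of 16 other libraries. Its lists numbered 5 without TRAF6i-HDL replicate 8, 8 without PBS replicate 2, 5 without 5, 1 without 7 and 0 without 8.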

Other observations

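The test of the proliferation list was chosen after the results were seen, and the other list results belong to the planned comparisons. Several lists passed in none of the 6 comparisons, and for each the lowest adjusted p over them is given. Those closest to the aims of the inhibitors were NF-kB target genes (0.0837), components of CD40 and TRAF6 signalling (0.844), mTORC1 pathway components (0.468), autophagy (0.145) and cholesterol biosynthesis (0.603). Metabolic and stress lists were glycolysis and HIF1A targets (0.423), fatty acid oxidation (0.104), amino acid response and ATF4 targets (0.248), inflammasome and IL-1 family (0.305), apoptosis (0.204) and extracellular matrix remodelling (0.0576). Cell type lists were fibroblasts (0.714), chondrocyte-like cells (0.432), cardiomyocytes (0.244), B cells (0.145), neutrophils (0.7), dendritic cells (0.224), adipocytes (0.145), erythroid cells and platelets (0.198) and Schwann cells (0.535). A list that did not pass is not shown to be unchanged.

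The proliferation list was lower in mTORi-HDL than in PBS, and the hypothesis tested was that this comes from 1 of the 2 sets of mTORi-HDL samples that the series lists apart. Without the 3 libraries under 200000 counts its mean log2 CPM differed from PBS by -0.86 ± 0.19 in replicates 1 to 4 and by -0.043 ± 0.17 in replicates 5 to 10, and over all samples by -0.77 ± 0.26 and 0.05 ± 0.23. The sets differed by -0.82 ± 0.21 (± 0.28 over all samples). This was found and tested on the same values, so it restates them, and Cdk1, a member, was below the PBS mean in 10 of 10 mTORi-HDL samples. No label says how these sets differ.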
